A study of Oryza sativa Japonica Group with 24 samples.

How the data were processed

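The data are Agilent oligonucleotide arrays of rice (Oryza sativa, Japonica group) leaves and roots, from plants transformed with OsCPK4 or with an empty vector and grown hydroponically for 15 days. Leaves were hybridised to 12 one-colour arrays labelled with Cy3, 3 for each of OsCPK4 lines 1 and 13 and empty vector lines 3 and 9. Roots were hybridised to 2 two-colour arrays, with OsCPK4 lines in Cy5 and vector lines in Cy3 per the labels. The series' own description speaks of leaves on 2-colour arrays, whereas the labels of the samples and the scanner files give 2 colours for roots and 1 for leaves, and the latter were followed. Per the labels, root RNA with an integrity number under 6 was discarded, and each root locus is read by 3 oligonucleotides used as technical replicates of 1 of 2 biological replicates. The 6 root samples that share a hybridisation hold the same file, so each hybridisation was counted once.

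The deposited scanner files hold spot intensity on a linear scale. Per the file headers, leaf intensities were extracted with Feature Extraction 10.7.3.1, which subtracted and detrended the background, and root intensities with Feature Extraction 10.5.1.1, with no background subtraction and no dye normalization in the processed signal. The authors also deposited a matrix of processed values for each tissue, log2 values for leaves and a score for roots. In the leaf matrix every column has a median of 9.79 and the same set of values, as quantile normalization leaves, and its columns correlate with the log2 scanner signal of their arrays at 0.966 to 0.975 across spots. In the deposited root matrix each score column has mean 0 and SD 1. Its medians are -0.203, -0.198 and -0.193 for line 1, -0.192, -0.186 and -0.188 for line 13, -0.195, -0.190 and -0.191 for vector line 11 and -0.226, -0.225 and -0.222 for vector line 3. How the root scores were scaled and whether they are logarithmic is not given in the sources used here. They behave as one channel each, not as ratios, and no ratio direction is stated for them. Array files carry gene descriptions for the leaf and none for the root, where a locus number is all that ties oligonucleotides together. The genome build of the probe coordinates is not given in the sources used here.

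Calculations used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the data.table package in version 1.17.8. For leaves, control spots and spots marked as outliers (48 to 78 per array) were left out, and the log2 processed signal minus the array's 75th percentile was averaged over spots of a probe. A probe was kept if well above background on all 3 arrays of at least 1 line, which kept 36128 of 42477 probes. The brightest probe stood for a gene, giving 24110 genes, of which 23972 have a RAP locus and 138 are probes or accessions without one. Of 2192 genes with several called probes, 65 (2.97%) had probes called in opposite directions. Where a gene was not well above background on any array of a group, the brighter group's mean was set against the higher, per array, of the lowest detected signal and its own. The result is given as a bound, which holds only under this background correction and scaling. For roots, normexp background correction with offset 50 and loess within arrays gave log2 ratios of Cy5 over Cy3, averaged over the oligonucleotides of a locus. The flag for signal above background was set on all root spots, so the planned filter removed none, although median signals are close to those of the negative control spots.

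The comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. Both lines labelled OsCPK4 were compared with both vector lines by limma (lmFit and eBayes with an intensity trend), with line as a random block through duplicateCorrelation, which estimated a correlation of 0.611 within lines. Each line against both vector lines, line 1 against line 13 and vector line 3 against line 9 were contrasts of 4 line means over all 12 arrays. Root log ratios were tested against 0. Adjusted p-values are Benjamini-Hochberg values from these limma fits over all genes tested, with a threshold of 0.05. An SE is that of the limma fit.

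The 20 gene lists were drawn from gene descriptions and fixed locus numbers: CDPK family, class III peroxidases, scavengers of reactive oxygen species, glutathione S-transferases, lipid metabolism and transfer, abscisic acid and dehydration response, salt and ion transport, pathogenesis-related proteins, WRKY factors, jasmonate and wounding, diterpenoid phytoalexins, photosynthesis, root tissue markers, dividing cells, heat shock and chaperones, cytosolic ribosomal proteins, circadian clock, iron deficiency, phosphate starvation and aquaporins. The photosynthesis, root and dividing cell lists serve as markers of tissue make-up. Lists were tested with cameraPR at a preset correlation of 0.01 and with camera and an estimated correlation, with Benjamini-Hochberg adjustment over the lists. The estimated test ran on the contrasts of line means, whose error leaves out the spread between lines. The description search put 33 of 169 genes into the pathogenesis-related list through the word methionine alone, and without them the list's median was 0.0046 (unadjusted p = 0.0707).

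Named genes of the leaf comparison are, in each direction, the 12 largest changes among described genes that passed and whose arrays did not overlap between the groups, or, where fewer passed, those plus the ones of smallest p up to 6. For the comparisons of lines they are the 5 largest in each direction, for each list up to 4 members of smallest p, and OsCPK4 and its paralogue OsCPK18 always. Only those that carry a comparison are printed. Alternatives were other background corrections, quantile normalization, other filters, slide or replicate number as a block, the mean over probes, the deposited matrices, other treatments of line, each line or array left out, a 2-fold threshold and no intensity trend. Added after the data were seen were each slide alone, the list without methionine, a root filter at the negative controls' mean plus 3 SD, another pairing of the root matrix columns and neighbours on the chromosome at 20 kb or more. Other splits of the arrays were refitted for at most 100 draws on the genes without missing values.

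The fits were tested on simulated data with 200 genes changed. For both lines against both vector lines, 65.7% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 97.0% of those changed 4-fold were recovered among 24110, with 21 false calls. The real comparison called 5 genes. That count cannot be set beside these false calls, since the 200 changed genes loosen the cut-off of the Benjamini-Hochberg adjustment. All genes of this simulation had the same correlation within lines, as the fit assumes, so genes with stronger line effects were not represented. For line 1 against the vector lines the shares were 82.1%, 91.0% and 100% (13 false calls), and for line 1 against line 13 they were 79.1%, 88.1% and 98.5% (13 false calls). Both comparisons of lines were simulated with the spread within lines alone. Their false calls therefore leave out genes that differ between lines without the transgene. For roots the shares were 37.3%, 86.6% and 90.9% among 44823 loci and probes (13 false calls). A simulated shifted list was called, as was 1 of 20 unshifted ones. Root gene lists, OsCPK4 in roots and genes shared by leaf and root were left out because the root files pair no probe with a gene name.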

Results

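Gene expression was measured in leaves and roots of rice plants carrying an OsCPK4 transgene and of plants carrying an empty vector, all grown in hydroponic culture for 15 days without treatment. OsCPK4 encodes a calcium-dependent protein kinase, an enzyme that phosphorylates other proteins when it binds calcium. The leaf data came from 12 one-colour arrays of 4 transgenic lines, with 3 arrays each of OsCPK4 lines 1 and 13 and of empty vector lines 3 and 9. The arrays were spread over 3 slides, each of which held 1 array of every line. The 75th percentile of the signal lay between 11.7 and 12.2 on the log2 scale, and 79.0% to 85.6% of probes were well above background. The root data came from 2 two-colour hybridisations, one of line 1 against empty vector line 11 and one of line 13 against empty vector line 3. The number of arrays and, above all, of lines limits the precision of every comparison. Nothing in the leaf labels says that arrays of a line came from separate plants, so p-values between lines measure the spread between these arrays, which may be technical.

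The OsCPK4 transcript was examined first in the leaf. OsCPK4 (Os02g0126400) was read by 3 probes that share 1 distinct sequence, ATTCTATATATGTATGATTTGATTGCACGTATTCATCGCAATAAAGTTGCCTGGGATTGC, placed by the array annotation on chromosome 2 from 1394211 to 1394270, with no genome build stated. Whether this site lies in a coding exon or an untranslated region, and inside the transgene, was not analysed here. Relative to each array's 75th percentile, the log2 signal of OsCPK4 was -0.79, -0.74 and -0.80 on the arrays of line 1 and 0.75, 0.73 and 0.75 on those of line 13. The arrays of empty vector line 3 gave 0.06, 0.02 and 0.13, and those of empty vector line 9 gave 1.61, 1.58 and 1.48. The order of the line means was thus empty vector line 9 at 1.56, line 13 at 0.74, empty vector line 3 at 0.07 and line 1 at -0.78. In line 1 the OsCPK4 signal fell by 1.59 ± 0.04 (SE) against the mean of both vector lines (adjusted p = 2.5e-11), whereas line 13 differed from that mean by -0.07 ± 0.04 (adjusted p = 0.219). With line as a random block, the difference between the lines labelled OsCPK4 and the vector lines was -0.83 ± 0.42 (adjusted p = 0.758), and within the 3 slides it was -0.85, -0.87 and -0.78. The OsCPK4 signal at this site was therefore not higher in both lines labelled OsCPK4, and the groups are called lines labelled OsCPK4 throughout. Whether this goes against the labels cannot be told, since a transgene transcript without the site would not be read. Its closest paralogue OsCPK18 (Os07g0409900) gave -0.00 ± 0.07 (adjusted p = 0.9997).

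**Figure D1:**
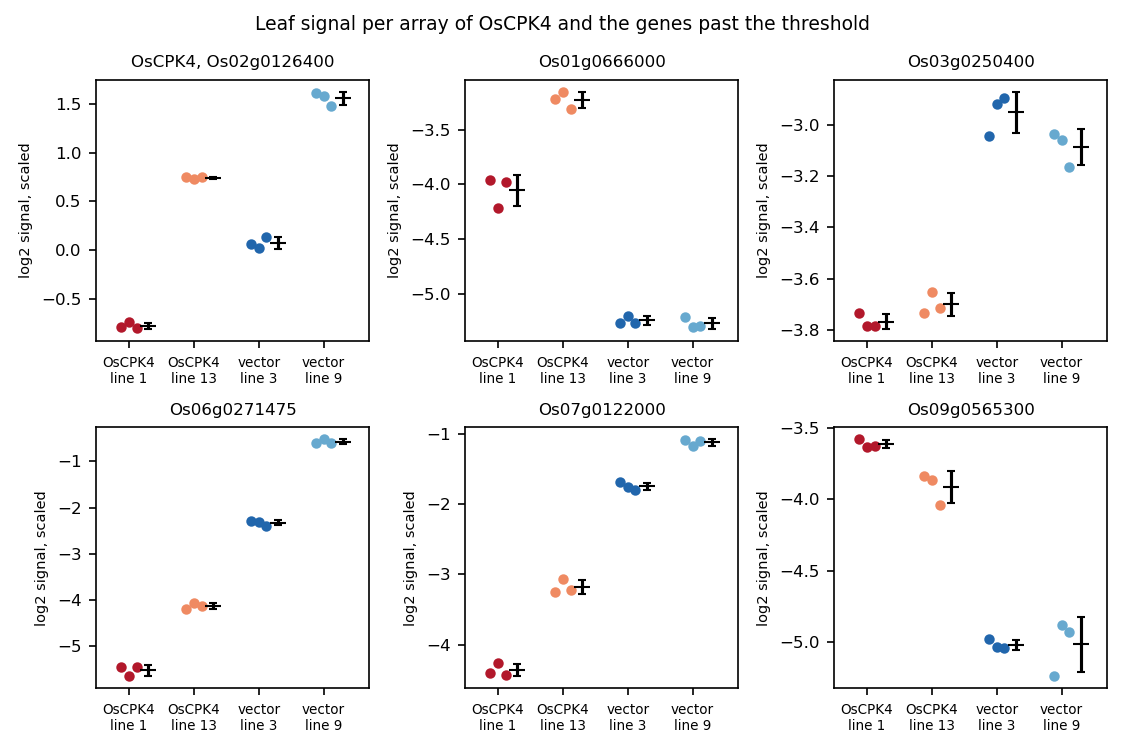
Log2 signal on each leaf array, relative to that array's 75th percentile, for OsCPK4 and the 5 genes that changed between the lines labelled OsCPK4 and the vector lines. Points are arrays and bars are the mean ± SD of the 3 arrays of a line; the OsCPK4 signal averages 1.56 in empty vector line 9 and -0.78 in line 1.

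To ask what the lines labelled OsCPK4 share against the vector lines in leaves, the arrays of both lines were compared with those of both vector lines (6 arrays each), with line as a random block. Os01g0666000, described as similar to a lipid phosphate phosphatase, rose by 1.62 ± 0.21 on the log2 scale (adjusted p = 0.0253), with line means of -4.06 and -3.23 against -5.25 and -5.27. Os09g0565300, described as similar to a RING-finger protein, a class that includes many ubiquitin ligases, rose by 1.25 ± 0.17 (adjusted p = 0.0253). Os03g0250400, with a plant lipid transfer protein domain, fell by 0.71 ± 0.10 (adjusted p = 0.0472). A further pair fell outside the rule for named genes and was chosen after its values were seen: Os06g0271475, without a description, at -3.36 ± 0.45 and Os07g0122000, with a domain of unknown function, at -2.34 ± 0.28 (both adjusted p = 0.0253). On the 3 slides taken one by one, Os01g0666000 gave 1.68, 1.48 and 1.69 and Os09g0565300 gave 1.20, 1.31 and 1.26. Os03g0250400 gave -0.71, -0.78 and -0.65, Os06g0271475 gave -3.41, -3.39 and -3.30, and Os07g0122000 gave -2.41, -2.30 and -2.30. Just short of the threshold lay the transcription factor gene WRKY62 (Os09g0417800) at 0.83 ± 0.12 (adjusted p = 0.0558), an amidase gene (Os04g0184100) at 0.89 (adjusted p = 0.0836) and a cytochrome P450 gene (Os11g0635500) at 0.80 (adjusted p = 0.0911). Lower by value without passing were Os09g0442700 at -1.05 (adjusted p = 0.0911), the rhodanese-like gene Os02g0157600 at -0.74 (adjusted p = 0.159) and Os02g0678800 (adjusted p = 0.235). As a bound Os02g0678800 was lower by 1.74 on the log2 scale, but it stood at -0.61 in the deposited matrix, so its size is not settled.

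Among 24110 genes tested by limma, 5 changed in this comparison, 2 of them higher and 3 lower in the lines labelled OsCPK4, and 1596 (6.62%) had an unadjusted p under 0.05. The direction is drawn from the labels, which the OsCPK4 signal at its probe site did not bear out. With slide as a block 0 genes passed by limma, and the 5 genes had the log2 differences given above at an adjusted p of 0.0928 to 0.184. With normexp background correction Os01g0666000 stood at 0.66 and Os09g0565300 at 0.50 (both adjusted p = 0.9963), and in the deposited matrix they stood at 0.955 and 0.753 (both adjusted p = 0.0941). Over 31 settings the adjusted p of the 5 genes ranged up to 0.9989. The count was 0 without replicate 1 or 3 of line 1, without replicate 1 of line 13, without any 1 replicate of empty vector line 3 and without replicate 3 of empty vector line 9. It was 1 without replicate 2 of line 13, 2 without replicate 2 of line 1, replicate 3 of line 13 or replicate 2 of empty vector line 9, and 7, WRKY62 among the genes then passing (adjusted p = 0.0497), without replicate 1 of empty vector line 9. Over these 12 fits Os07g0122000 passed in 5, Os09g0565300 in 3, Os01g0666000 in 2, Os06g0271475 in 1 and Os03g0250400 in 0 (adjusted p = 0.0503 to 0.130). Other ways to treat the lines and the background moved the count further. It was 546 without the random block and 8496 with only the spread within lines as the error. Both of these fits count arrays, although the genotype was set per line. The count was 0 with averages of lines, where each line counts once, and 0 with normexp background correction.

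The 20 gene lists were then compared with all other genes. The jasmonate and wounding list, which holds genes of the synthesis and signalling of this wound hormone, fell by a mean of 0.26 over 51 genes (adjusted p = 5.4e-05, and adjusted p = 0.00766 with an estimated correlation). Its allene oxide synthase gene (Os03g0225900), an early step of jasmonate synthesis, stood at -0.70 ± 0.20, and a Tify gene (Os03g0180800) at -1.86 ± 0.72. Another member, Os12g0247700, went the other way, at 1.02 to 1.13 with each array left out in turn. The iron deficiency list of 12 genes fell by a mean of 0.73 (adjusted p = 0.00043, and 0.0282 as the adjusted p with an estimated correlation), led by nicotianamine synthase genes, whose product chelates metals. NAS1 (Os03g0307300) stood at -3.01 ± 0.66 and NAS2 (Os03g0307200) at -2.90 ± 0.69, whereas NAS3 (Os07g0689600) stood at 0.72. The CDPK family, 28 genes including OsCPK4 itself and 2 whose descriptions name a substrate of such kinases, fell by a mean of 0.13 (adjusted p = 0.00253, and adjusted p = 0.0282 with an estimated correlation), with Os04g0584600 and Os07g0568600 both at -0.49. The test with an estimated correlation has only the spread within lines as its error, so passing it does not tell genotype from line. Between the vector lines the jasmonate list (-0.48) and the CDPK family (-0.34) passed both tests too, whereas the iron deficiency list (-0.59) passed only the preset one.

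A further 5 lists passed with the preset correlation only. WRKY factors, which regulate defence genes, had a mean of -0.16 over 63 genes (adjusted p = 0.0269, and adjusted p = 0.117 with an estimated correlation), although WRKY62 and WRKY76 (Os09g0417600) stood at 0.83 and 0.93. Markers of dividing cells had a mean of -0.20 over 79 genes (adjusted p = 0.00161, and adjusted p = 0.117 with an estimated correlation), among them the histone H2A gene Os05g0113900 at -1.01, whose line mean was 0.39 in empty vector line 9 and -1.57 to -1.45 in the other lines. Cytosolic ribosomal protein genes averaged -0.07 over 136 genes (adjusted p = 1.2e-09, and adjusted p = 0.409 with an estimated correlation of 0.264, above the preset 0.01). With normexp background correction their mean of -0.06 no longer lay below the median of all genes, -0.06. The preset test nevertheless kept its call in 31 of 31 settings (adjusted p up to 0.00994). By value, untested, the list averaged -0.064 and -0.060 in line 1 against vector lines 3 and 9, and -0.082 and -0.078 in line 13. Between the vector lines its mean was 0.0038 (adjusted p = 0.855 with the preset correlation). Photosynthesis genes averaged 0.13 over 44 genes (adjusted p = 0.00846, and adjusted p = 0.607 with an estimated correlation), and aquaporins 0.26 over 12 genes (adjusted p = 0.00145, and adjusted p = 0.282 with an estimated correlation).

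The other 12 lists did not pass. Their means and adjusted p were -0.05 and 0.114 for class III peroxidases (98 genes), 0.02 and 0.479 for scavengers of reactive oxygen species (39 genes), 0.02 and 0.811 for glutathione S-transferases (50 genes), and 0.01 and 0.95 for lipid metabolism and transfer (244 genes). Genes of the response to abscisic acid and dehydration gave -0.04 and 0.0861 (42 genes), salt and ion transport 0.06 and 0.409 (71 genes), pathogenesis-related proteins -0.02 and 0.283 (169 genes), and diterpenoid phytoalexins 0.05 and 0.911 (11 genes). Root tissue markers gave 0.67 and 0.124 (4 genes), heat shock and chaperone genes 0.07 and 0.210 (130 genes), clock genes -0.12 and 0.210 (9 genes), and phosphate starvation genes 0.00 and 0.911 (35 genes). Median and mean differed in sign for peroxidases, abscisic acid, pathogenesis-related and clock genes, and the test pointed down against a positive mean for glutathione S-transferases and phosphate starvation genes. Adjusted over the list alone, 2 iron deficiency genes (NAS1 and NAS2) fell, WRKY62 and the root-specific gene RCc3 (Os02g0662000) rose, and 2 peroxidase genes (1 higher, 1 lower), 1 glutathione S-transferase gene (lower) and 1 lipid gene (lower) changed, against 0 in the other lists. The size for RCc3 is not settled, since its log2 difference ran from 0.246 to 3.56 over 29 settings. Over all genes tested only the lipid list had a called member, Os03g0250400.

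The signs of the called lists' means held under each scaling, and all passed with slide as a block, where the adjusted p was 4.3e-05 for jasmonate and wounding, 0.000722 for iron deficiency, 0.00446 for the CDPK family and 0.0342 for WRKY factors. It was 0.00215 for dividing cells, 2.2e-09 for ribosomal proteins, 0.0223 for photosynthesis and 0.00221 for aquaporins. On slides 1, 2 and 3 the means were -0.21, -0.29 and -0.26 for jasmonate and wounding, -0.70, -0.86 and -0.63 for iron deficiency, and -0.17, -0.07 and -0.14 for the CDPK family. Those of WRKY factors were -0.11, -0.23 and -0.15. Those of dividing cells were -0.17, -0.24 and -0.20, of ribosomal proteins -0.05, -0.10 and -0.06, of photosynthesis 0.26, 0.02 and 0.09, and of aquaporins 0.32, 0.20 and 0.27. The WRKY call ended without replicate 3 of line 1 (adjusted p = 0.0534), the photosynthesis call without replicate 1 of empty vector line 3 (0.0725), with quantile normalization (0.102) and in the deposited matrix (0.119), and the dividing cell call with normexp (0.227). The WRKY call also ended with no filter on dim probes (0.0837), with the mean over probes (0.0734) and without an intensity trend (0.0553). Single lines carried several of these shifts, among them those of the 3 lists that passed both tests. Without line 1 the jasmonate list averaged -0.04 (adjusted p = 0.704), the CDPK family -0.01 (adjusted p = 0.383), photosynthesis 0.07 (adjusted p = 0.340), aquaporins 0.15 (adjusted p = 0.310) and the WRKY list 0.14 (adjusted p = 0.0245). Without line 13 the iron list averaged -0.30 (adjusted p = 0.513) and the dividing cell list -0.17 (adjusted p = 0.296), and without empty vector line 3 the WRKY list averaged -0.23 (adjusted p = 0.132). Without empty vector line 9 the jasmonate list averaged -0.02 and the CDPK family 0.05 (both adjusted p = 0.891), the dividing cell list 0.02 (adjusted p = 0.665), the iron list -0.36 (adjusted p = 0.165), the WRKY list -0.10 (adjusted p = 0.442) and aquaporins 0.17 (adjusted p = 0.103), and photosynthesis turned sign at -0.01 (adjusted p = 0.457).

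Each line labelled OsCPK4 was also set against both vector lines, with 3 arrays against 6 and the spread within lines as the error. In line 1, WRKY genes fell by a mean of 0.46 (27 lower and 7 higher of 63; adjusted p = 2.0e-20, and adjusted p = 0.0311 with an estimated correlation). The jasmonate and wounding list fell by a mean of 0.47 (26 lower, 6 higher), with the Tify gene Os03g0180800 at -3.52 (adjusted p = 2.7e-12) and allene oxide synthase (Os03g0225900) at -1.16 (adjusted p = 2.4e-09). The CDPK family fell by a mean of 0.24 (12 lower, 2 higher), and heat shock and chaperone genes rose by a mean of 0.18 (53 higher, 11 lower). For these lists the adjusted p with an estimated correlation was 0.00466, 0.0281 and 0.0281. The iron deficiency list did not pass in line 1, at a mean of -0.30 (4 higher and 5 lower of 12; adjusted p = 0.121). Abscisic acid and dehydration genes averaged 0.20 (adjusted p = 0.0377, and adjusted p = 0.508 with an estimated correlation), and aquaporins 0.37 (adjusted p = 0.0261, and adjusted p = 0.244 with an estimated correlation). Set against vector lines 3 and 9 separately, by value and untested, the lists of line 1 averaged -0.39 and -0.52 for WRKY genes, -0.23 and -0.71 for jasmonate, and -0.07 and -0.42 for the CDPK family. Heat shock genes averaged 0.17 and 0.18, and abscisic acid and dehydration genes, with opposite signs, 0.55 and -0.15. The abscisic acid call of line 1 also ended without replicate 1 of line 1 (adjusted p = 0.0693), replicate 1 of empty vector line 3 (0.0881) or replicate 1 or 3 of empty vector line 9 (0.0528 and 0.0523). It ended too with normexp, at a mean of 0.02 (0.112), with quantile normalization (0.110), with only probes well above background on all 12 arrays (0.0573), with the mean over probes (0.140) and in the deposited matrix (0.0724). The aquaporin call of line 1 ended with quantile normalization (0.0633), no filter on dim probes (0.0639), only probes well above background on all 12 arrays (0.0535) and in the deposited matrix (0.0724).

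In line 13, iron deficiency genes fell by a mean of 1.16 (8 lower and 1 higher of 12; adjusted p = 2.1e-51, and adjusted p = 0.00587 with an estimated correlation), with NAS1 (Os03g0307300) at -4.34 and NAS2 (Os03g0307200) at -4.29. Abscisic acid and dehydration genes averaged -0.28 against the mean of both vector lines (21 lower, 1 higher; adjusted p = 2.8e-14, and adjusted p = 0.0384 with an estimated correlation). The CDPK family did not pass in line 13, at a mean of -0.01 (4 higher and 9 lower of 28; adjusted p = 0.218). WRKY genes averaged 0.14 in line 13 (17 higher, 8 lower; adjusted p = 0.00238, and adjusted p = 0.436 with an estimated correlation). Dividing cell markers averaged -0.24 (adjusted p = 2.0e-05, and adjusted p = 0.0972 with an estimated correlation), ribosomal proteins -0.08 (adjusted p = 0.000301, and adjusted p = 0.436 with an estimated correlation), and jasmonate genes -0.04, with a median of 0.01 (adjusted p = 0.0296, and adjusted p = 0.181 with an estimated correlation). Set against each vector line by value, untested, the abscisic acid list of line 13 averaged 0.07 against line 3 and -0.63 against line 9, and dividing cell markers -0.01 and -0.47. Likewise, jasmonate genes averaged 0.20 and -0.28, and iron deficiency genes -0.86 and -1.45. The jasmonate call of line 13 ended without replicate 2 of line 1 (adjusted p = 0.051) or of line 13 (0.0535) and with normexp (0.0530).

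By count, 9652 genes changed in line 1, 6012 higher and 3640 lower, and 5262 in line 13, 3006 higher and 2256 lower. With normexp background correction the split was 2093 higher and 1931 lower in line 1 and 679 higher and 620 lower in line 13, and with quantile normalization that of line 13 turned to 2508 higher and 2547 lower. Genes called on any pair of slides had the same sign on the slide left out in 93.2% to 95.5% of cases for line 1 and 97.8% to 99.4% for line 13. With slide as a block the counts were 11236 and 6758. The lists of both lines shared 1634 higher and 1239 lower genes, where independent lists of these sizes would share 749.6 and 340.6, and 819 genes were called in opposite directions. Across genes the log2 differences correlated at 0.267 with a covariance of 0.0336. Both comparisons use the same vector arrays, and simulated unchanged lines against those arrays gave a correlation of 0.329 and a covariance of 0.0065 from the spread within lines alone, with 0 shared genes, and 0.337 and 0.0551 with spread between lines added, where they shared 1544.5 higher and 1550.5 lower genes. With the vector lines split, line 1 against line 3 and line 13 against line 9 shared 970 and 633 genes (676.0 and 321.5 for independent lists), with 1523 opposite and a correlation of -0.150, covariance -0.0288. The opposite assignment shared 394 and 210 (662.6 and 301.3 for independent lists), with 2174 opposite and a correlation of -0.235, covariance -0.0420.

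**Figure D2:**
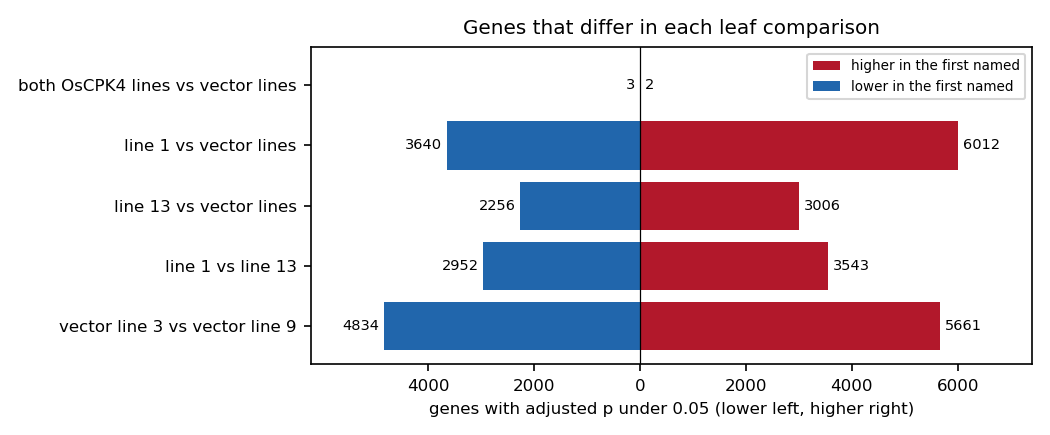
Number of leaf genes higher and lower (adjusted p under 0.05, limma) in each comparison of lines. Bars to the right of 0 count genes higher in the first-named side and bars to the left genes lower. With line as a random block, 5 genes changed between the lines labelled OsCPK4 and the vector lines. With the spread within lines as the error, 10495 differed between both vector lines.

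The lines labelled OsCPK4 were compared directly to see whether they changed alike. A gene with an ACT domain (Os02g0608600) was far higher in line 13, at -7.55 ± 0.06 for line 1 minus line 13, and its line mean was 6.27 in line 13 and between -1.45 and -1.27 in the other lines. A gene similar to CRT/DRE binding factor 1 (Os02g0677300), a class of cold and drought regulators, was at -6.76 ± 0.09, an amino acid transporter gene (Os01g0597600) at -6.62 ± 0.07 and a Tify gene (Os10g0391400) at -5.24 ± 0.09. Higher in line 1 were the ZIP8 gene (Os05g0472400), of a metal transporter family, at 5.29 ± 0.19 and an integrase gene (Os11g0224300) at 5.20 ± 0.45. Their size is not settled, since they were well above background on 1 and 2 of the 3 arrays of line 13 and stood at 2.89 and 2.75 with normexp background correction. With only probes well above background on all 12 arrays, ZIP8 stood at 0.97 (adjusted p = 0.164). The WRKY list was lower in line 1 by a mean log2 difference of -0.59 (adjusted p with an estimated correlation 0.0113) and the jasmonate list by -0.43 (0.00882), whereas the iron deficiency list was higher by 0.86 (0.00882), heat shock genes by 0.21 (0.00882) and scavengers of reactive oxygen species by 0.18 (0.0398). The CDPK family differed by -0.23 (0.0337), and abscisic acid and dehydration genes by 0.47 (adjusted p = 1.3e-11, and adjusted p = 0.0777 with an estimated correlation). In all, 6495 genes (26.9%) differed, 3543 higher and 2952 lower in line 1. With normexp 1268 were higher and 1396 lower, and with slide as a block 7897 differed. Of genes called on any pair of slides, 97.8% to 99.4% had the same sign on the slide left out.

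The vector lines were compared with each other to see how far lines of the same label differ, although the OsCPK4 signal was highest in vector line 9. WRKY69 (Os08g0386200) was higher in line 3 than in line 9 by 2.53 ± 0.04 and a gene for a vesicle-associated membrane protein (Os07g0249200) by 3.06, the latter 0.82 (adjusted p = 0.109) with normexp background correction. A MULE transposase gene (Os07g0627100) and a xyloglucan fucosyltransferase gene (Os04g0449200) were lower in line 3, with bounds of -5.65 and -3.34, and stood at -3.77 and -1.68 in the deposited matrix. A cytochrome P450 gene (Os05g0211100) was also lower in line 3, but was well above background on only 1 of its 3 arrays there, so the size of this difference is not settled. It was -5.64 ± 0.89 by the fit, -3.59 with normexp background correction and -2.77 in the deposited matrix. A bound is used where a gene was not well above background on any array of one line, and sets the brighter line against the dimmest detected signal. It holds only under the main background correction and scaling. Abscisic acid and dehydration genes were lower in line 3 by a mean difference of -0.70, jasmonate genes by -0.48 and the CDPK family by -0.34, with adjusted p of 0.0373, 0.0186 and 0.0373 with an estimated correlation. With the preset correlation only, peroxidases (-0.31), pathogenesis-related proteins (-0.21), dividing cell markers (-0.45), iron deficiency genes (-0.59), photosynthesis genes (0.27) and diterpenoid phytoalexin genes (0.56, but -0.77 with normexp) also passed, where the adjusted p with an estimated correlation was 0.346, 0.455, 0.346, 0.424, 0.505 and 0.455. With normexp the calls of pathogenesis-related proteins (-0.50, adjusted p = 0.205) and dividing cell markers (-0.60, adjusted p = 0.638) ended. The mean over probes ended those of pathogenesis-related proteins (0.0519) and diterpenoid genes (0.146), and no filter on dim probes that of diterpenoid genes (0.0545). In all, 10495 genes (43.5%) differed, 5661 higher and 4834 lower in line 3, and 11881 with slide as a block. With normexp 6270 differed and the balance turned, with 2776 higher and 3494 lower. Of genes called on any pair of slides, 97.1% to 97.9% had the same sign on the slide left out.

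**Figure D3:**
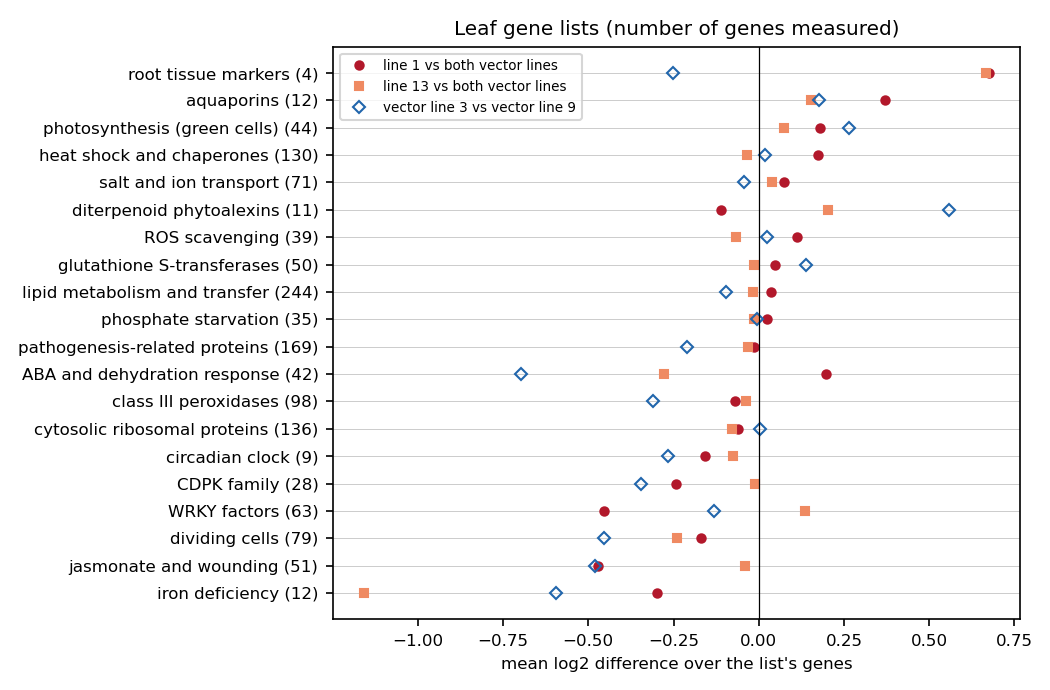
Mean log2 difference over the genes of each of the 20 lists, for line 1 and line 13 against both vector lines and for empty vector line 3 against line 9. The iron deficiency list averages -1.16 in line 13, and the abscisic acid and dehydration list averages -0.70 between the vector lines.

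The 4 lines can be paired in 3 ways. The labelled pairing called 5 genes, line 1 with vector line 3 against line 13 with vector line 9 called 1093, and the remaining pairing called 454. In the labelled pairing both lines of one side lay beyond both lines of the other for 29.2% of genes, where chance gives 33.3%; the other pairings gave 44.5% and 26.3%. Arrays of a line correlated across genes at 0.993 to 0.997 and arrays of different lines at 0.974 to 0.992.

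In roots the same question was put to 2 hybridisations, each of 1 line labelled OsCPK4 in Cy5 against 1 vector line in Cy3, with 0 dye swaps, so that dye and genotype cannot be told apart. The files do not pair the root probes with gene names, so OsCPK4 and the gene lists were not analysed in roots. The smallest p among probes higher in the Cy5 channel belonged to locus 2584 at a log2 ratio of 1.25 ± 0.17 and locus 3381 at 0.83 ± 0.12, and among lower ones to a probe without a locus number at -1.17 ± 0.11 and locus 22831 at -0.54 ± 0.08. None of these passed (adjusted p = 0.669). Over 44823 loci and unassigned probes, 0 changed by limma and 3315 (7.40%) had an unadjusted p under 0.05. The log ratios of the hybridisations correlated across loci at 0.0225 (Spearman 0.107), 56% had the same sign, and at 2-fold or more on both, 0 were higher, 2 lower and 5 opposite. With median centring in place of loess 301 changed, and with the processed signals without loess 24750, of which 24400 were lower in Cy5. Taken alone, with no replicate, the line 1 hybridisation held 401 and the line 13 hybridisation 106 loci or probes at 2-fold or more. Over all loci, the signals of the line 1 hybridisation correlated (Spearman) at 0.355 to 0.718 with the deposited matrix columns of its samples, and those of the line 13 hybridisation at 0.709 to 0.969. Across the 6000 brightest loci by mean signal the ranges were 0.136 to 0.171 and 0.933 to 0.936. There the columns of the line 1 hybridisation's samples correlated with the signals of the line 13 hybridisation at 0.923 to 0.931. Median Cy5 and Cy3 signals were 56.4 and 62.4 for line 1 and 80.7 and 90.5 for line 13, against negative control means of 37.6 and 50.9, and 37.4 and 48.1.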

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

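Tests of the probe site, of the slide, of spot noise and of the file of the line 1 hybridisation were chosen only after the result was seen.

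The first pattern is the OsCPK4 signal (Os02g0126400), which was lower in line 1 than in line 13 by a log2 difference of -1.52 and highest in empty vector line 9. If line 1 and vector line 9 had exchanged labels, pairing line 13 with vector line 9, the lines of highest OsCPK4 signal, should separate the lines better than the labelled pairing. It called 1093 genes against 5, but the remaining pairing, which this exchange does not predict, also called more, at 454. An exchange stays open, though 1 of the 3 pairings must call the most and the order of 4 lines by one gene is weak evidence. The gene was read at 1 distinct probe site, and a transcript of the transgene that lacks this site might escape detection, which no second site could test. A biological difference in how far each line expresses the transgene was not tested.

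The second pattern is that the vector lines differ from each other at 10495 genes. Lines 1 and 13 differ from the mean of both vector lines at 9652 and 5262. These are unlike measures, a line against a line and a line against the mean of a pair. Line 1 against line 13, also a line against a line, gave 6495. The tables argue against the slide as the cause, since at least 97.1% of genes called on any pair of slides had the same sign on the slide left out, and against array scaling, since 10629 genes differed after quantile normalization. Time of harvest in the day stays open: the median absolute difference of 9 clock genes was 0.299, below the 95th percentile of 0.328 in 10000 random lists of matched signal, but by less than its own spread (bootstrap SD 0.139), and 7 of the 9 were called, GIGANTEA (Os01g0182600) at -0.49 among them. Harvest on different days, growth position and changes in the genome of each line stay open, and a biological difference between lines was not tested by design.

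The third pattern is that the root hybridisations gave unrelated log ratios (correlation 0.0225 across loci). Spot noise is argued against, since the oligonucleotides of a locus correlated at 0.926 or more within each hybridisation. Whether the file for line 1 holds another hybridisation than the one behind the deposited matrix stays open, since the values move with the loci chosen. Over all loci, the line 1 hybridisation correlated (Spearman) at 0.355 to 0.718 with the matrix columns of its own samples and the line 13 hybridisation at 0.709 to 0.969, ranges that touch. Across the 6000 brightest loci the ranges were 0.136 to 0.171 and 0.933 to 0.936 by mean signal, which lowers the first, and 0.272 to 0.436 and 0.880 to 0.962 over the other choices.

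Of 100 splits of the arrays drawn, the labelled one among them and slide left out of the fits, 6 called at least as many genes as the 5 of the labelled groups, with the highest other at 2417, so chance was not excluded. Why that split called so many was not tested. For line 1 against the vector lines only the real split, with 9640 genes, reached that count among 100 drawn (1 of them the real one, highest other 3848). For line 13 likewise only the real split did, with 5258 (highest other 4914). This cannot exclude chance, since splits other than exchanges of whole lines mix arrays of different lines, which widens the error within groups. Arrays of a line stay close together, and most exchanges of whole lines, which are among the possible splits, gave more. Vector line 9 against line 1 and vector line 3 called 12208 genes. Vector lines 9 and 3, each against line 13 and the other vector line, called 11004 and 8221. Vector line 3 against line 1 and vector line 9 called fewer, 6794. Line 1 against line 13 and vector line 3 against line 9 have 10 splits each, too few for a share under 0.05, with 6487 and 10479 genes in the real split and 0 in the highest other.

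The lines labelled OsCPK4 differed by a direct test at 6495 genes. Among the genes called in both lines together, line 1 minus line 13 was -0.83 for Os01g0666000, -1.39 for Os06g0271475, -1.19 for Os07g0122000 and 0.30 for Os09g0565300, so these differed in amount, whereas Os03g0250400 did not pass, at -0.07 (adjusted p = 0.482). Among the lists, the same difference was -0.23 for the CDPK family, 0.18 for scavengers of reactive oxygen species, -0.59 for WRKY factors, -0.43 for jasmonate and wounding, 0.21 for heat shock and chaperones and 0.86 for iron deficiency. In the root files, which the comparisons use without control spots, the Cy5 signal of the control probes eQC-40 was 174.5 in the line 1 hybridisation, above the limit of 41.7 set by the negative controls, and that of eQC-41 was 49.35 in the line 13 hybridisation, above 41.5.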

How the results depend on the processing

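Tests of each slide alone, of the root filter at negative controls and of the crossed root pairing were chosen after the data were seen. Of 106 main values outside left-out arrays 72 held, and of 2329 values of single genes and lists 1984 held, 98 lost and 215 gained a call and 32 turned sign. In this count a list turned by the direction of its test, not by its mean, and a gene that stayed uncalled counts as held. Over 31 settings, each array left out among them, the 5 genes called in the main comparison held in 8 to 17. The count of 5 became 0 with normexp, 2 with quantile normalization, 12 with no filter, 9 with the mean over probes, 3 with the matrix, 546 without a line block, 8496 with 4 line means (whose error leaves out the spread between lines), 0 with averages of lines and 0 on slide 1, 2 or 3 alone. It was 45, 288, 4440 and 109 without line 1, line 13, vector line 3 and vector line 9, and 0 to 7 without each array. With slide as a block it was 0. As a replicate block the titles' numbers gave 0 genes, and 8751, 4279, 5533 and 9740 in the line comparisons, but these numbers do not pair the arrays: same-numbered arrays deviated together at -0.43 to 0.50 (median -0.06, 5 of 18 pairs over 0.1), and 1 of 12 arrays went best with its own number. Slide did pair the arrays: those of a slide deviated together at a median of 0.33 (14 of 18 pairs over 0.1, 9 of 12 arrays best with their own slide), whereas the comparisons were fitted without slide unless stated. With normexp the line comparisons called 4024 (line 1), 1299 (line 13), 2664 (line 1 against 13, 1268 higher and 1396 lower) and 6270 (vector lines, 2776 higher and 3494 lower); without each array they stayed at 7806 to 9689, 3576 to 5350, 5047 to 6823 and 9344 to 10333. The OsCPK4 difference passed with 4 line means (-0.83, adjusted p = 3.1e-09) and without vector line 3 (-1.58, adjusted p = 0.0285), and ran from -0.88 to -0.79 without each array; over its settings the adjusted p ran from 3.1e-09 to 0.9998. Of 20 lists 8 passed, against 3 with an estimated correlation, 5 without line 1, 4 without vector line 9, 5 on slide 2 alone and 7 to 9 without each array. These counts include other lists than the 8: of the 8, dividing cells, ribosomal proteins and iron deficiency kept their call and sign without line 1, and ribosomal proteins without vector line 9. These turned sign. With normexp, which moved the median of all genes from 0.043 to -0.064 in the main comparison, from 0.060 to -0.11 for line 1, from 0.030 to -0.10 between lines 1 and 13 and from 0.019 to -0.26 between vector lines: Os01g0210700 -0.18, Os12g0491800 -0.016, Os10g0551800 -0.045, Os04g0521100 -0.23, Os02g0658100 -0.092 and, between vector lines, Os06g0141400 -0.081; relative to these medians Os12g0491800, Os10g0551800 and Os06g0141400 stayed higher. Without line 1: Os02g0570400 0.25, Os10g0551800 -0.15, Os02g0745100 -0.26 and the WRKY list 0.14. Without line 13: Os10g0349300 0.34 and Os07g0409900 0.043. Without vector line 3: Os02g0570400 0.13. Without vector line 9: Os04g0435500 0.031, Os08g0139700 -0.028, Os08g0119800 -0.045, Os02g0745100 -0.11, Os10g0349300 0.10, Os05g0493500 0.017, Os03g0279200 0.0019, Os02g0618200 0.019, Os01g0182600 0.0024, Os11g0157600 0.0021, Os07g0409900 0.054, photosynthesis -0.0070 and, by its test, jasmonate at -0.018. By mean but not by test, the CDPK family (0.053) and dividing cells (0.021) also turned without vector line 9. So did the diterpenoid list between vector lines with normexp (-0.77). With the matrix: Os07g0409900 0.0017. On slide 1: Os10g0349300 0.037 and Os07g0409900 0.0048. On slide 2, by its test: photosynthesis 0.025. On slide 3: Os10g0349300 0.0013 and Os07g0409900 0.012. Without each array Os07g0409900 ran from -0.016 to 0.015 and Os10g0349300 from -0.15 to 0.046. In roots 0 genes became 24750 with processed signals without loess, 301 with median centring, 17 with the matrix and 149 with its pairing crossed; at 2-fold with no test there were 2 on both hybridisations, 106 on that of line 13 and 401 on that of line 1. Beyond what a setting's construction shows, the cause was not tested. Root gene lists, OsCPK4 in roots and leaf and root shared genes were not run. Dim spots limit all of this: at least 79.0% of leaf probes were well above background, but root medians of 56.4 to 90.5 lie near negative controls at 37.4 to 50.9.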

Other observations

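The tests of the root matrix columns and of neighbours at 20 kb or more were chosen after the result was seen, whereas that of all neighbours within 100 kb was written before.

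A pair of DREB1 genes and a Tify gene, chosen after their values were seen, had low signals in line 1, with no test of a group behind them. DREB1B (Os09g0522000) had a line mean of -1.11 in line 1 against 3.87 in line 13, 3.53 in empty vector line 3 and 2.30 in empty vector line 9, and DREB1A (Os09g0522200) had -0.80 against 2.98, 2.57 and 2.27. The gene between them by locus number, Os09g0522100, similar to another C-repeat binding factor, was 2.35, 2.28, 2.19 and 2.03 in the same order, and the list of abscisic acid and dehydration genes was not lower in line 1 than in line 13, at a mean difference of 0.47. The Tify gene Os10g0391400 was -3.52 in line 1 and 0.69 to 1.72 in the other lines.

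Empty vector line 9 stood apart from the other lines. On the first principal component of all genes, which held 40.2% of the variance, its arrays lay at 53.1 to 53.9 and those of the other lines at -29.2 to -4.24. Set against pairs of other lines, vector line 9 differed from line 1 and vector line 3 at 12208 genes and from line 13 and vector line 3 at 11004, whereas vector line 3 differed from line 1 and vector line 9 at 6794 and from line 13 and vector line 9 at 8221.

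A hypothesis is that lines of one genotype differ in part through chromosome segments, such as changes that arose in tissue culture. It predicts that genes at least 4-fold different have neighbours within 100 kb, of another description, that differ at least 4-fold in the same direction, more often than random genes of matched signal. Between line 1 and line 13, 21 of 177 such genes (11.9%) had one, against a 95th percentile of 19 and a highest value of 32 in 10000 random sets. Between the vector lines 56 of 278 did (20.1%), against 47 and 67. Between line 1 and line 13, however, 6 of these genes are pairs of one family that the array describes differently (NAS1 and NAS2, DREB1A and DREB1B, and the phosphate-induced genes Os02g0756800 and Os02g0757100), and 15 remain without them. With neighbours at 20 to 100 kb, which leaves out these pairs, and others as close in the random sets, 6 genes had one between line 1 and line 13, against a 95th percentile of 16, and 35 between the vector lines, against 40. So no excess was seen beyond 20 kb, closer neighbours may be related or regulated together, and whether segments differ between lines stays open.

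In the deposited root matrix the columns of line 1 correlated across loci with those of vector line 3 at 0.987, but with those of vector line 11, its partner on the array, at 0.492. Columns of line 13 correlated at 0.754 with vector line 3, its partner, and at 0.765 with vector line 11. Differences between partners as labelled correlated between the pairs at -0.793 and with partners exchanged at 0.044.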
